A study of Mus musculus with 4 samples.

How the data were processed

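Messenger RNA was profiled on 4 Affymetrix mouse arrays. One array held RNA of an induced pluripotent stem cell (iPSC) clone made from tail-tip fibroblasts with adenoviral vectors, and 3 held RNA of embryonic stem cell (ESC) lines derived after nuclear transfer (NT) from that clone. Per the labels' protocols, the cells grew in serum and LIF on irradiated mouse embryonic fibroblasts, were replated for a short time to take the fibroblasts away, and total RNA was labelled with biotin by in vitro transcription. The software and settings of the array normalization and summarization were not given in the sources used here.

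The deposited values were on a log2 scale, but not log2 intensities. On each array the mean of 2 raised to the deposited value was 1, and these ratios ran from 0.422 to 2.03, so a value had the form of the log2 of a probe set's log intensity over the array's mean log intensity. Differences between deposited values are therefore not log2 fold changes. The plan made before the data were examined had been to use log values as given; instead each value was turned back into a level on the log2 intensity scale by multiplying the ratio by an assumed mean log2 intensity of 7, which puts the brightest probe set at 14.2. That mean is not held in the table. A mean of 6 makes every log2 difference 14.3% smaller, and a mean of 7.86, at which the brightest probe set reaches the 16-bit limit of 16, makes it 12.3% greater; limma's p-values do not depend on it. Levels, folds and counts of genes past a fold limit carry this uncertainty.

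The table held 45101 probe sets, of which 64 were controls. The platform annotation gave 1 gene for 34945 probe sets, several for 932 and none for 9160, and no gene was named from a probe set with several. Gene IDs of 34741 probe sets were found in the RefSeq table of assembly GRCm38.p6, which was used for symbols, chromosomes and gene order; the files name no build, so no coordinates are given. Each of 18193 genes was represented by its probe set with the highest mean over the 4 arrays. The median level of all probe sets was 6.83, and genes with a mean at or above it are called bright below. The number of arrays limits the precision.

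The NT-ESC lines were compared with the iPSC clone by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). With 1 iPSC array the spread came from the 3 NT-ESC arrays alone (2 residual and 3.57 prior degrees of freedom), and the lone iPSC array was assumed to vary like them. The labels call the lines subclones without saying whether they came from separate derivations, and no line had a second array. SDs, SEs and limma's p-values for single genes therefore measure the spread between these 3 arrays, which are not known to be independent derivations. For 1 line against the others they measure the spread of the clone and the other 2 lines taken as 1 group. Genes at least 2-fold apart from every array of the other side were counted without a test. A gene was counted only if its brighter side reached the median level of all probe sets. The same limit held for pairs of arrays and for probe sets without a single gene. Of 32 gene lists fixed before the data were examined, holding 600 symbols of which 545 were measured, 31 with at least 5 measured genes were tested by limma's camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, and set against 10000 random lists matched on mean level. The genes of 20 chromosomes with at least 100 measured genes, a limit set after the data were seen, were tested by camera and fry in the same way, but not against random lists; only chromosome 8 in line 3 was set against random gene sets, 1000 of them. The test of each NT-ESC array against the other 3 by limma was also added after the data were seen. With the preset correlation, camera compares a list with all other genes. Its p-value rests on the spread across genes and the assumed correlation, and does not measure variation between lines. With an estimated correlation, camera has at most the 2 residual degrees of freedom, so a call is hard to reach. Chromosome 1 in line 3 lost its call there although its estimated correlation was -0.000159.

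The genes named in the text follow a rule fixed before the data were examined: up to 10 genes in each direction past the threshold, which gave none; the Dlk1-Dio3 cluster, X inactivation and Y-linked genes; 7 pluripotency genes; up to 4 members of each list by size; up to 5 genes in each direction for each NT-ESC line; and RNA quality controls. Others are said to be chosen after their values were seen. The fit was tested on simulated data of 3 arrays against 1 with 200 of 18193 genes changed, in 5 runs. It recovered 2.69% of genes changed by 0.5 log2, 82.1% of those changed by 1 and 97.9% of those changed by 2, with 9.6 false calls per run on average. A simulated list of 16 genes shifted by 0.3 log2 was recovered in 20 of 20 runs by camera with the preset correlation. The simulated genes varied independently, whereas the hypoxia list had an estimated correlation of 0.358. The simulation therefore does not show how far a list call can be trusted. The alternatives were quantile normalization, centring on the median, other rules for probe sets, a filter on dim genes, other variance models and thresholds, each array left out, other scale factors, the deposited values used as given, and chromosome 8 genes left out.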

Results

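Gene expression was measured in 1 iPSC clone and in 3 NT-ESC lines derived from it, on 1 array each. Reprogramming by nuclear transfer exposes the donor genome to the egg cytoplasm, and the series sets the parental clone beside its derivatives. Across the 18193 genes the arrays correlated with Pearson's r of 0.9951 to 0.9979; genes are not independent replicates. Levels below are log2 intensities with the array mean set to an assumed 7, so log2 differences scale with that choice.

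The 7 pluripotency genes named beforehand differed by at most 0.15 log2 between the iPSC clone and the mean of its NT-ESC lines. Without line 3 the largest differences were 0.37 for Dppa3, -0.26 for Myc and 0.23 for Nanog. Pou5f1, which encodes Oct4, stood at 12.22 in the clone and at 12.22 ± 0.02 (SD, n = 3) in the lines. Sox2 stood at 12.40 and 12.52 ± 0.09, and Nanog at 12.05 and 12.20 ± 0.14. Klf4 differed by 0.14 ± 0.08 (SE), Zfp42 by 0.15 ± 0.08 and Myc by -0.14 ± 0.18. Dppa3, an oocyte and germ cell factor, ranged from 8.55 in line 3 to 9.88 in line 1, with 9.32 in the clone. None of these 7 genes passed limma's test. Of the 15 measured core pluripotency factors, 5 were higher and 5 lower in all 3 lines, and their median log2 difference was -0.045. The list was not called (limma camera, Benjamini-Hochberg adjusted p = 0.876). Its median was nevertheless lower than that of nearly all random lists matched on level (percentile 1.10). Without line 3 the median was 0.0201, at percentile 44.60.

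No gene passed limma's test between the NT-ESC lines and the clone. The smallest Benjamini-Hochberg adjusted p was 0.856, while 629 genes were higher and 377 lower in the lines at an unadjusted p under 0.05. Among genes whose brighter side reached the median level, none was 2-fold higher or lower against every line. At 1.5-fold, Zdbf2, a paternally expressed imprinted gene, was higher in every line, and Gm9564, chosen after its value was seen, was lower. The following genes were chosen after their values were seen, as those with large gaps to all 3 lines. Zdbf2 stood at 8.21 in the clone and at 8.94, 9.01 and 9.57 in the lines. Tfcp2l1, a transcription factor of naive pluripotency downstream of LIF and STAT3, stood at 10.11 in the clone and at 10.68 to 10.84 in the lines. Lefty1, an inhibitor of Nodal signalling, stood at 10.54 in the clone and at 9.60, 10.14 and 8.45 in the lines. By chance, 25% of genes have the clone as the lowest array and 25% as the highest.

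The imprinted transcripts of the Dlk1-Dio3 cluster, whose maternally expressed noncoding RNAs are often silenced in mouse iPSCs, were measured for 4 genes. Meg3 stood at 9.04 in the clone and 9.38 ± 0.20 (SD, n = 3) in the lines, Rian at 7.42 and 7.37 ± 0.09, and Dlk1 at 6.93 and 6.63 ± 0.16. Mirg differed by -0.03 ± 0.08 (SE). Among 40 imprinted genes of other loci the median log2 difference was -0.00635, and 0.0469 without line 3. Phlda2 differed by -0.47, Cdkn1c by -0.40 and Copg2 by 0.39. None passed limma's test. Xist, the RNA that silences the X chromosome, differed by -0.02 ± 0.08. The Y-linked Uty stood at 6.59 in the clone and at 5.84 to 5.94 in the lines, Kdm5d at 6.30 and 6.09 to 6.14, and Eif2s3y at 7.92 and 7.08 to 8.18. The Tsix difference was -0.12.

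Of the 31 lists, 9 shifted between the NT-ESC lines and the clone by camera with the preset correlation, 6 up and 3 down. With an estimated correlation none of them was called (limma camera, Benjamini-Hochberg adjusted p = 0.854 for cholesterol synthesis and 0.841 for the other 8). That form of the test has at most 2 residual degrees of freedom here, so it cannot decide whether a list shifted. The 2-cell-like genes lost the call although their estimated correlation was -0.071, below the preset 0.01. The 16 hypoxia genes rose the most as a list, with a median log2 difference of 0.276, and 14 of them were higher in all 3 lines (limma camera, Benjamini-Hochberg adjusted p = 2.71e-08). Among them Ero1a, an oxidase of the endoplasmic reticulum, differed by 0.50 ± 0.10 (SE), Egln1, an oxygen-sensing prolyl hydroxylase, by 0.49 ± 0.21, and Ndrg1 by 0.48 ± 0.14; Egln1 lies on chromosome 8. The 16 glycolysis genes had a median of 0.11, and 11 were higher in all 3 lines (limma camera, Benjamini-Hochberg adjusted p = 8.35e-06); Pfkp, a phosphofructokinase, differed by 0.51 ± 0.09 and the hexokinase Hk1 by 0.44 ± 0.11. Of the 19 p53 targets 14 were higher in all 3 lines, with a median of 0.218 (limma camera, Benjamini-Hochberg adjusted p = 8.35e-06); line 3 carried much of the size, since the median was 0.116 without it. Perp differed by 0.49 ± 0.16 and Trp53inp1 by 0.39 ± 0.08. The 17 naive state genes had a median of 0.133, with 10 higher in all 3 lines (limma camera, Benjamini-Hochberg adjusted p = 0.000511), among them Tfcp2l1 at 0.65 ± 0.09 and Tbx3 at 0.48 ± 0.10. The 13 primed epiblast genes had a median of -0.31, with 7 lower in all 3 lines (limma camera, Benjamini-Hochberg adjusted p = 0.00245), and of -0.174 without line 3. Lef1 differed by -0.53 ± 0.24, Sox3 by -0.41 ± 0.11 and the DNA methyltransferase Dnmt3b by -0.36 ± 0.24.

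These 5 lists were also called when each NT-ESC line was left out in turn. The other 4 lost the call without 1 line. The cholesterol synthesis list (median 0.0916, limma camera, Benjamini-Hochberg adjusted p = 0.0131) had 0.239 without line 1, the LIF-STAT3 targets (median 0.101, adjusted p = 0.00483) had 0.0982 without line 1, the X inactivation and Y-linked list (median -0.174, adjusted p = 0.00939) had 0.121 without line 1, and the 2-cell-like genes (median -0.169, adjusted p = 0.0412) had 0.107 without line 2. With the mean of probe sets the X inactivation and Y-linked list (limma camera, Benjamini-Hochberg adjusted p = 0.214), the LIF-STAT3 targets (0.0607) and, narrowly, the 2-cell-like genes lost the call. Without dim genes cholesterol synthesis lost it (limma camera, Benjamini-Hochberg adjusted p = 0.094), and the 2-cell-like and the X and Y lists were too small to test. No list was called with fry (smallest Benjamini-Hochberg adjusted p = 0.651). No list member passed over all genes. Adjusted over the list alone, 4 glycolysis genes, 2 naive state genes, and 1 each of the hypoxia, LIF-STAT3 and X and Y lists passed. The lists share members, so their calls are not independent. Tfcp2l1 belongs to both the naive state and the LIF-STAT3 list and passed in each, and Pdk1 and Slc2a1 belong to both the glycolysis and the hypoxia list. The other 22 lists had medians from -0.104 for Wnt targets to 0.0926 for immediate early genes. They included the fibroblast and feeder genes (0.0221), primitive endoderm (0.0365), trophectoderm (-0.00986) and germ line genes (0.0306). The fibroblast and feeder median was 0.0871 without line 3 and -0.00598 without line 2. The germ line median was -0.0195 without line 2. The ratios on the iPSC array had a slightly smaller SD, 0.2788 against 0.2817 to 0.283 on the others; genes with a mean level over 10 had a median difference of 0.029 and those under 6 of -0.0395. That array also had the smallest gap between the 3' and 5' probe sets for 3 of 4 control genes, with Actb at 0.218 against 0.276 to 0.421. It was the lowest for all 4 hybridization controls, with cre at 13.74 against 13.85 to 13.95, so an effect of that array on the list differences was not excluded. Random lists matched on level had an upper bound of 0.0952 for the hypoxia median and 0.0955 for the p53 median, both below the values found. The cholesterol synthesis median, 0.0916, lay under its upper bound of 0.102 (percentile 95.38). The LIF-STAT3 median, 0.101, stood at its upper bound of 0.101 (percentile 97.63). An offset that depends on level was therefore not excluded for cholesterol synthesis and barely so for the LIF-STAT3 targets. The medians of the remaining called lists lay outside their bounds.

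**Figure D1:**
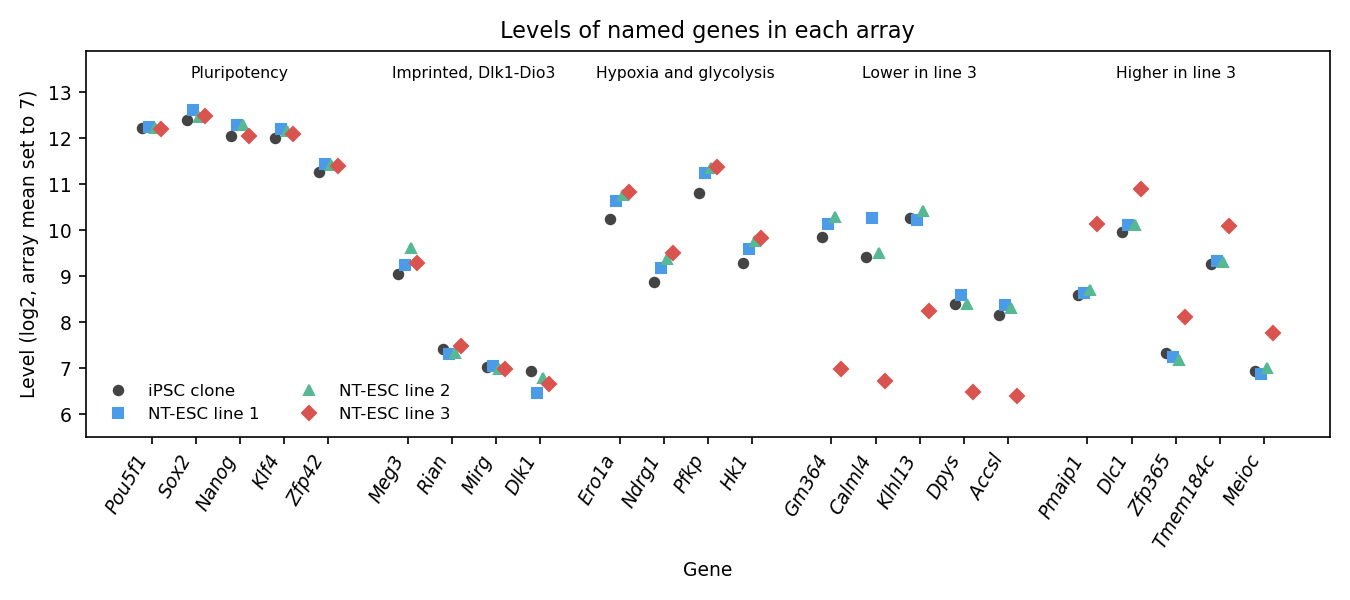
Levels of named genes on each array (log2 intensity with the array mean set to 7; 1 point per array, grouped by gene list or by line 3). The 5 pluripotency genes shown, which leave out Dppa3 and Myc, lay close together on all 4 arrays, while Gm364 stood at 6.97 in NT-ESC line 3 against a mean of 10.09 on the other arrays.

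NT-ESC line 3 stood apart from the clone and from the other lines by counts of genes. The counts by limma are not a like comparison, since line 3 adds to the spread whenever another array is singled out. For Pmaip1, for example, the SD of the other 3 arrays was 0.05 for line 3, 0.86 for line 1 and 0.88 for line 2. Counts of genes 2-fold apart use no spread, but leave out genes whose brighter side lay under the median level. When each array was set against the other 3 by limma, with the spread of the other 3 taken as that of the lone array, 84 genes were called for line 3, 29 higher and 55 lower (smallest Benjamini-Hochberg adjusted p = 0.00104), and 0 for line 1, line 2 or the clone. At an unadjusted p under 0.05 the counts were 2104 for line 3, 504 for line 1, 423 for line 2 and 1006 for the clone. Of genes 2-fold apart from each other array, line 3 had 23, of which 22 were lower, and the other arrays had 0. Pairs that held line 3 had 30, 42 and 31 genes at least 2-fold apart, and the other pairs had 2 or 3. The mean over pairs of clone and line was 11.7 and over pairs of lines 25. With 4 ways to single out 1 array, no share below 0.25 can be reached, and leaving out any 1 of the other arrays left 0 calls by limma, with 1 residual degree of freedom, while the 2-fold count was then 24 to 26.

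The X-linked Gm364 fell by 3.12 on the log2 scale in line 3, and Calml4, a calmodulin-like gene, fell by 3.02. Klhl13, an adaptor of a ubiquitin ligase that is also X-linked, fell by 2.06. Dpys, which encodes an enzyme of pyrimidine breakdown, fell by 1.99, and Accsl fell by 1.89. Their limma Benjamini-Hochberg adjusted p-values were 0.00104, 0.0146, 0.00104, 0.00114 and 0.00114. Pmaip1, the p53 target that encodes the pro-apoptotic protein Noxa, rose most, by 1.49 ± 0.08 (SE), from a mean of 8.64 on the other arrays to 10.14 (limma, Benjamini-Hochberg adjusted p = 0.0012). Zfp365 rose by 0.85 and Meioc, a meiosis gene, by 0.83. Dlc1 rose by 0.83 and Tmem184c by 0.79, and both lie on chromosome 8, whose genes were higher in line 3 as described below. Chosen after their values were seen, the imprinted genes Peg3 and Sfmbt2 differed by -0.92 and -1.28, Morc1, a germ line gene that silences transposons, by -1.34, and the transcription factor Jun by -0.61, all past the threshold. Of the lists, 3 were called for line 3 against the other arrays, each with an adjusted p of 0.765 with an estimated correlation: the p53 targets (median 0.213, 15 of 19 highest there, limma camera, Benjamini-Hochberg adjusted p = 4.39e-09), the hypoxia genes (0.153, 10 of 16 highest, adjusted p = 0.00075) and the primed epiblast genes (-0.263, 8 of 13 lowest, adjusted p = 0.00627). The core pluripotency factors were the 1 list called by fry in any contrast, lower in line 3 with a mean of -0.103 and a median of -0.0226, 7 of 15 lowest and 3 highest (limma fry, Benjamini-Hochberg adjusted p = 0.0038, and 0.139 by camera).

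Genes on chromosome 8 were higher in line 3 than on the other 3 arrays. Over all 932 measured genes the median log2 difference was 0.18, and 616 were highest in line 3 (limma camera, Benjamini-Hochberg adjusted p = 1.57e-33, and 0.0597 with an estimated correlation; fry, which tests the set by itself, gave 0.0193). Of the 636 bright genes of chromosome 8, 522 (82.1%) were highest in line 3, against 2610 of 11111 (23.5%) on other chromosomes. The median rose with level, from 0.00903 for genes under 6 to 0.367 for genes over 10. Of the 29 genes called higher, 17 lay on chromosome 8, where 1.49 would be expected. They included Cbfb, the partner of Runx factors, at 0.64 (chosen, like Sall1, after its value was seen), the heat shock cochaperone Dnajb1 at 0.70, the collagen gene Col4a1 at 0.80 and Ankrd37, a hypoxia gene, at 0.82. Sall1 was the 1 lower call on that chromosome, at -0.62. Chromosome 1 was also higher (median 0.0407, limma camera, Benjamini-Hochberg adjusted p = 0.000988) and the X chromosome lower (-0.0494, adjusted p = 0.0072), with adjusted p of 0.0597 and 0.178 with an estimated correlation. Between all NT-ESC lines and the clone, chromosome 8 was the 1 chromosome called (median 0.0578, limma camera, Benjamini-Hochberg adjusted p = 0.0171, and 0.847 with an estimated correlation), and without line 3 none was.

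**Figure D2:**
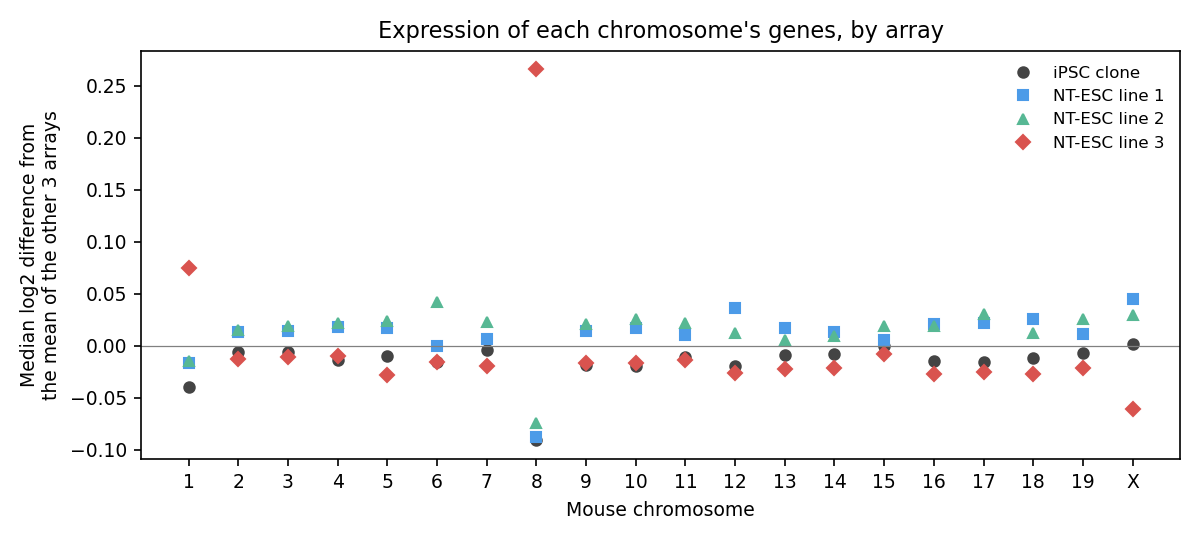
Median log2 difference of the bright genes of each chromosome from the mean of the other 3 arrays, 1 point per array. Line 3 stood at 0.266 for chromosome 8, against -0.091 for the clone, -0.0878 for line 1 and -0.074 for line 2, and at 0.0748 for chromosome 1. A rise on 1 array lowers the values of the other 3 by construction. Between lines 1 and 2 and the clone, the median over all chromosome 8 genes was -0.00275.

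No gene was called for line 1 or line 2, and their named genes are values that passed no test. In line 1, Calml4 stood at 10.26 and Sp5, a Wnt target, at 7.98, both higher than on the other arrays, and Usp17la stood at 6.52 and Krcc1 at 7.89, both lower. Against the other arrays 6 lists were called for line 1, each with an adjusted p of 0.94 with an estimated correlation. Higher were cholesterol synthesis (median 0.1, limma camera, Benjamini-Hochberg adjusted p = 0.000213), the LIF-STAT3 targets (0.106, adjusted p = 0.00157) and the naive state genes (0.174, adjusted p = 0.00708). Lower were the X inactivation and Y-linked list (-0.252, adjusted p = 0.00708), the 2-cell-like genes (-0.169, adjusted p = 0.00858) and the MHC class I genes (-0.126, adjusted p = 0.0159; limma camera, Benjamini-Hochberg). In line 2, Slit2, a guidance ligand, stood at 8.02 and Malat1, a nuclear noncoding RNA, at 11.47, both highest there, while Apela, an embryonic stem cell peptide hormone, stood at 8.62 and was lowest. The fibroblast and feeder list was higher in line 2 than on the other arrays (median 0.127, 19 of 33 genes highest there, limma camera, Benjamini-Hochberg adjusted p = 2.02e-05, and 0.907 with an estimated correlation). Col3a1 stood at 9.89 in line 2 and at 9.44 to 9.57 on the others. Line 2 also had the largest gap between the 3' and 5' probe sets for all 4 control genes; for Actb it was 0.421 against 0.218 to 0.293.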

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

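All of the tests of explanations in this part were chosen after the results were seen, and no biological explanation was given by the design for a difference between the NT-ESC lines.

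The median log2 difference of chromosome 8 genes in NT-ESC line 3, 0.18, stood out in a test of that line against the other arrays. Array scaling that depends on level is argued against, since the highest median of 1000 random gene sets matched on level was 0.00433. A few neighbouring genes do not account for it either, since 10 of 10 equal parts of the gene order had bright-gene medians above 0.1, from 0.187 to 0.358; nor does the choice of probe set, since 422 bright probe sets not used had a median of 0.302. A candidate explanation is an extra copy of chromosome 8 in cells of line 3: genes over level 10 had a median of 0.367, below the 0.585 that 3 copies over 2 would give in every cell. The assumed scale did not make up the gap, since the same genes had 0.412 with the scale at the 16-bit limit; whether a part of the cells or compressed array signal does was not tested, and no DNA was analysed here.

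The 84 genes called in line 3, 55 of them lower, stood out in a test of the line against the other arrays, which gave 0 for each other array singled out. Those counts of 0 are partly built in, since line 3 adds to the spread when another array is singled out. For 13 of the lower genes, 22 other bright probe sets had a median of -0.654, which argues against the choice of probe set. For the other 42 no second bright probe set decides. Dilution by feeder fibroblasts or other cells would lower the 15 core pluripotency factors by about the -0.915 median of the lower genes, but their median was -0.0226 with an SD of 0.185, far from that size even though fry called them lower (mean -0.103, limma fry, Benjamini-Hochberg adjusted p = 0.0038), and the fibroblast list stood at -0.0514. Lower RNA quality of line 3 is argued against through line 2 alone. Line 2 had 3' to 5' gaps at least as large for all 4 control genes and no gene counted as 2-fold apart from each other array. Line 3 had larger gaps than the clone and line 1 for all 4, with Actb at 0.293 against 0.218 and 0.276. A difference acquired by the line stays open as untested.

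As a list the hypoxia genes were higher in the NT-ESC lines (median 0.276), 14 of 16 in all 3 lines. The call was lost with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p = 0.841), where the few residual degrees of freedom make a call hard to reach. Array scaling that depends on level is argued against by the upper bound of matched random lists, 0.0952, and chromosome 8 in line 3 by the median of lines 1 and 2 alone, 0.221. The RNA quality or labelling of the iPSC array stays open, since it had the smallest 3' to 5' gap for 3 of 4 control genes and was the lowest for all 4 hybridization controls, and there was no second iPSC array. The state of the 1 iPSC culture when RNA was taken cannot be told apart from a difference between clone and lines, since there was 1 iPSC array.

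No comparison used the 10092 probe sets without a single named gene. Among those whose brighter side reached the median level, 2 were 2-fold lower in line 1 than on each other array. In line 3, 2 were 2-fold lower, against 0 for the clone and line 2.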

How the results depend on the processing

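The other scale factors, the deposited values used as given, the tests of line 3 and the setting without chromosome 8 were chosen after seeing the data. No gene was called between the NT-ESC lines and the clone under any alternative run. Runs without 1 NT-ESC line left 1 residual degree of freedom and could hardly call a gene. Line 3 likewise lost all its calls at that size. No paired analysis was possible because 1 iPSC array stood against all 3 NT-ESC lines. The planned pseudocount was not run, since the table was not linear; lists and chromosomes were not run for every probe set on its own, nor fold counts for the deposited values as given. At 1.5-fold in place of 2-fold, 1 gene was higher and 1 lower in every line, the mean over pairs was 95 for clone and line and 127 for line and line, and lines 1, 2 and 3 had 4, 1 and 82 genes apart. A mean log2 intensity of 6 gave pair means of 7.67 and 15.7 and 14 genes for line 3; the 16-bit limit gave 18.7 for clone and line and 1 gene for line 2. Leaving out single arrays gave pair means of 2.5 to 16.5 and 2 to 42, the lowest without line 3, and counts of 0 to 3 for line 1, 1 for line 2 and 24 to 26 for line 3, where fewer arrays had to be exceeded. The 84 calls of line 3 became 131 with quantile normalization, 168 with the mean of probe sets, 47 with every probe set on its own, 152 with trend and robust variances, 297 at an adjusted p under 0.1, 25 with treat, 51 without chromosome 8 and 15 with the deposited values as given, of which 84, 73, 39, 84, 84, 25, 51 and 15 were shared; the count was 0 without any 1 of the other arrays. With the values as given 1 of the 15 was higher, against 29 of 84. Lists called fell from 9 to 0 with an estimated correlation and with fry, and chromosomes from 1 to 0 with an estimated correlation and to between 0 and 1 with arrays left out, 0 without line 3. With an estimated correlation the test had at most 2 residual degrees of freedom, so those losses do not decide whether a list or chromosome shifted. The mean of probe sets and the filter on dim genes left 6 lists each and the deposited values as given 8, without the 2-cell-like genes. Quantile normalization left 7 lists, with the 2-cell-like genes at 0.057 and cholesterol synthesis at 0.131 (limma camera, Benjamini-Hochberg adjusted p). Except where noted the cause was not tested. Of 1599 values of 124 named genes under alternatives, 1541 moved by less than the SD of the lines and 14 had the opposite sign. The chromosome 8 median in line 3 differed by level, 0.00903 under level 6 and 0.367 over level 10.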

Other observations

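The trophectoderm genes were not called as a list between lines 1 and 2 and the clone (median 0.00934, limma camera, Benjamini-Hochberg adjusted p = 0.569). Of its members, Krt8 stood at 9.62 and 9.35 in lines 1 and 2 against 8.39 in the clone and 8.41 in line 3, and Krt18 at 9.37 and 9.08 against 8.30 and 8.01, as values that passed no test. Cell cycle genes were not called as a list between the lines and the clone (median 0.0465, limma camera, Benjamini-Hochberg adjusted p = 0.202), with Mki67, a proliferation marker, at 10.34 in the clone and 10.69 to 10.81 in the lines. Without line 3 the median of the cell cycle genes was 0.00507. The de novo methyltransferase Dnmt3a stood at 10.50 in the clone and in line 3 and at 10.02 in lines 1 and 2.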
